A study of Homo sapiens with 5 samples.

How the data were processed

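CUT&Tag libraries of 786-O cells were grouped from the labels as H4K12la control (2 libraries), H4K12la with 10 µM dexamethasone for 48 h (2 libraries) and GR with dexamethasone (1 library). All 5 carry the same batch label. Nothing in the labels says that replicates came from separate cultures, so tests measure the spread between these libraries, which may be technical. Replicate numbers are shared between the H4K12la groups without a stated link.

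Reads were trimmed with fastp 0.19.6 and aligned with Bowtie2 to GRCh38 (hg38), and deepTools was used, per the submitters' processing notes. The peak caller, its settings, any control library and any blacklist are not given in the sources used here. The authors deposited 1 peak list per library. The H4K12la lists have no header and give position, length, summit and a whole-number signal, the height at the summit as deposited by the authors, laid out like a pileup column. These heights belong to the authors' peaks and were used to rank and filter peaks within a list. Where heights of a gene are printed for several lists they are set side by side as deposited, and a difference between lists can come from depth. The lowest heights were 9, 10, 11 and 12, and the median heights 24, 26, 23 and 24, in control replicates 1 and 2 and dexamethasone replicates 1 and 2. The GR list gives positions and lengths, with no height. Its rows are numbered 1 to 15183 with gaps, and the 8065 rows used here are 53.1% of that range, for a reason that is not stated. Positions are 1-based. Total read counts are not given, so depth is unknown, and a longer list can come from a deeper library.

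Peaks on chromosomes 1 to 22, X and Y were kept, leaving out 2.51%, 2.41%, 2.02% and 2.03% of the H4K12la peaks and none of the GR peaks. Peaks of the 4 H4K12la lists sharing 1 bp were merged. A library held a region, or a gene end, when a peak overlapped it by 1 bp or more. Control-only means a peak in both control and neither dexamethasone library, and dexamethasone-only the reverse. Positions of 20037 protein-coding genes came from a RefSeq table of GRCh38.p14. The design called for windows around transcription start sites, but that table has no strand, so windows of 1 kb around both ends of the gene span were used instead, and 36.3% of genes share a window with another gene. The lower-coordinate end of the gene span, whichever strand the gene is on, was used to check the build. In control replicate 1, 41.8% of these ends had a peak, against 19.1% of positions shifted by 100000 bp. For GR the shares were 16.9% and 1.60%.

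Peak numbers were compared by an exact permutation test, two-sided. Region and gene counts were set beside the other splits of the 4 libraries. Gene lists (11, fixed before the data were examined) were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Genes are not independent replicates, and these tests describe these libraries. GR overlap was tested against 200 random placements, and GR overlap of region classes with Fisher's exact test and a Cochran-Mantel-Haenszel test. Share intervals are 95% exact binomial (Clopper-Pearson). The named genes are the 10 control-only and 10 dexamethasone-only genes with the highest mean percentile rank of their end peak, the 10 longest GR peaks (in place of a score, which the GR list lacks), list members that were control-only, dexamethasone-only or had a GR peak, up to 4 per list in the same order, and 8 genes fixed in advance. List members named beyond these 4, and RPL7, NQO1, AGAP9, ADAP1 and other genes in all 4 lists, were chosen after their values were seen.

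Alternatives were stricter heights, equal peak numbers, other overlap, merging and window rules, the replicate number as a block, and leaving out each replicate. The search for GR motifs was not run because no genome sequence was used here. The code was tested on simulated peak lists: 200 of 200 planted control-only genes among 10767 genes were recovered with 0 false calls, and 8 of 200 random lists passed an unadjusted Fisher's exact test at 0.05. The planted genes had no close neighbours and simulated replicates were identical, so full recovery checks the code and gives no error rate for these data. Loss in the random lists was drawn separately for each gene, unlike in genes that share windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.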

Results

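The series profiled chromatin of 786-O cells, an established human renal carcinoma line, by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA around its target. The targets were lactylated lysine 12 of histone H4 (H4K12la), a histone mark made from lactate-derived acyl groups, and the glucocorticoid receptor (GR), a transcription factor activated by dexamethasone. H4K12la was profiled in 2 untreated control libraries and in 2 libraries from cells given 10 µM dexamethasone for 48 h, and GR in 1 library from dexamethasone-treated cells. The deposited control lists held 129848 and 115182 H4K12la peaks, the dexamethasone lists 82382 and 68980, and the GR list 8065. Read depth is unknown for every library, so peak numbers and summit heights are not scaled to it. All values below are for chromosomes 1 to 22, X and Y of GRCh38.

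The first comparison asked how dexamethasone altered the H4K12la landscape. Peaks numbered 119502 ± 10030 (SD, n = 2) in control cells and 74152 ± 9291 (SD, n = 2) in dexamethasone-treated cells, a ratio of 0.621. Peaks within 1 kb of either end of a protein-coding gene, where the promoter lies at one of the ends, numbered 15182 ± 334 (SD, n = 2) and 7234 ± 1002 (SD, n = 2), a ratio of 0.476. The gene table gives no strand, so an end peak of any gene named below can lie at the end away from the promoter. The ribosomal protein gene RPL7 carried a peak at an end in all 4 libraries, with summit heights of 334 and 368 in control and 33 and 30 in dexamethasone libraries, and NQO1, a quinone reductase gene, had heights of 274 and 244 against 26 and 34. AGAP9 (59 and 52 against 80 and 82) and ADAP1 (41 and 50 against 61 and 59) had higher values in the dexamethasone lists. Of 4737 genes with an end peak in all 4 lists, both dexamethasone heights were below both control heights for 3893 and above both for 262, on a scale not adjusted for depth and without a test. Both group differences were larger than the spread between replicates, but the exact permutation test, two-sided, gave p = 0.333, the smallest value that 6 assignments of 4 libraries allow.

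Gene ends made up a smaller share of the highest peaks in the dexamethasone lists. Of the 5000 highest peaks of each list, 40.2% and 45.9% lay at gene ends in control libraries, with 95% exact binomial intervals of 38.8 to 41.6% and 44.5 to 47.3%. In dexamethasone libraries the shares were 11% (10.1 to 11.9%) and 10.4% (9.53 to 11.2%). Those peaks touched 2511 and 2870 genes in control and 647 and 612 genes in dexamethasone libraries. In the whole lists, gene ends held 12.2% and 13.3% of control peaks and 9.84% and 9.65% of dexamethasone peaks. Intervals cover counting error only, and the choice of 5000 peaks was made after the data were examined.

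**Figure D1:**
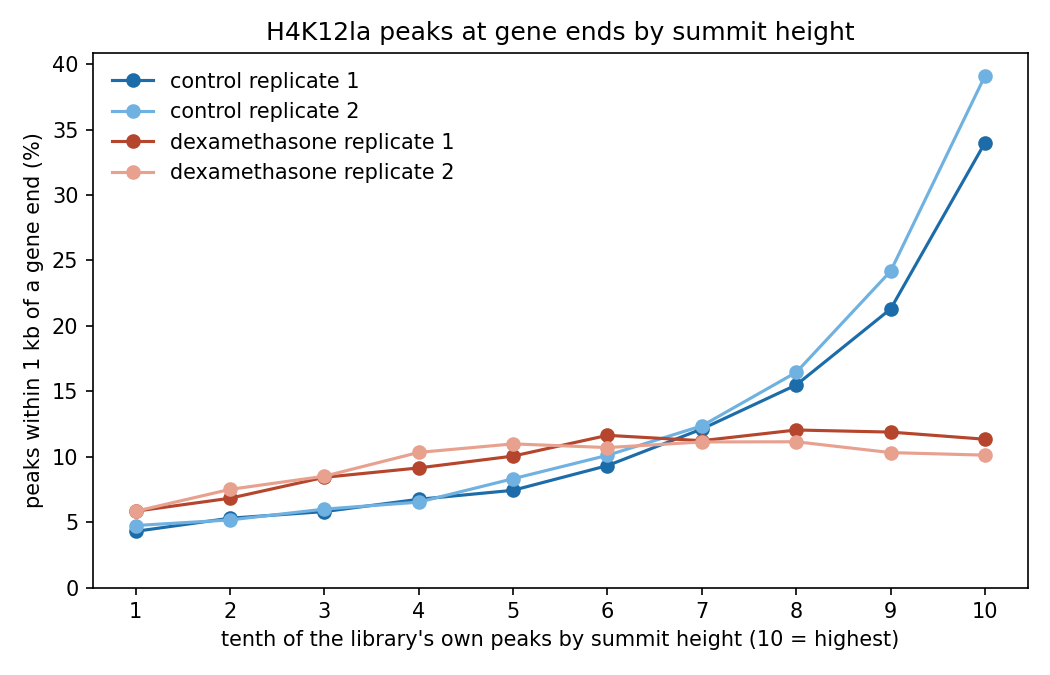
Share of H4K12la peaks within 1 kb of a gene end (y axis, percent) in each 10% of a library's own peaks ordered by summit height (x axis, highest on the right), with a line for each of the 4 libraries. In the highest 10% the share was 34.0% and 39.1% in control and 11.3% and 10.1% in dexamethasone libraries.

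Merging the peaks of the 4 libraries gave 184761 regions. Both control lists and neither dexamethasone list held 33206 of them, and 5744 were held by both dexamethasone lists and neither control list. Another 21206 regions in both control lists were in just 1 dexamethasone list. Of dexamethasone replicate 1 peaks, 50.9% overlapped replicate 2 and 63.1% overlapped control replicate 1. Of dexamethasone replicate 2 peaks, 60.7% overlapped replicate 1 and 66.2% overlapped control replicate 1, though a longer list is overlapped more easily. Between control replicates the shares were 67.8% and 75.8%. Gene ends made up 16.1% of the control-only regions, 4.04% of the dexamethasone-only regions and 15.6% of the 29445 regions present in all 4 lists. Of the regions in both control lists, 40.5% of those at gene ends and 39.4% of those elsewhere were in neither dexamethasone list. Compared within each 10% of control height, gene ends were absent from both dexamethasone lists more often than other regions, at a common odds ratio of 1.30 (95% interval 1.25 to 1.35). The exceptions were the highest 10%, where they were absent less often (22.8% against 27.6%), and the lowest 10% (49.6% against 50.2%). The other splits of the 4 libraries gave 4642 against 2232 regions (replicates 1 against replicates 2) and 3234 against 3024 (crossed), and 3 splits cannot give a p below 0.333. At equal peak numbers, with 67582 peaks taken from each list, the counts were 19273 control-only and 13138 dexamethasone-only regions. Leaving out a library loosens the definition, and the control-only count was 52907 without control replicate 1 and 62496 without control replicate 2, while the dexamethasone-only count was 9503 without control replicate 1, 17922 without dexamethasone replicate 1 and 24017 without dexamethasone replicate 2.

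At the level of genes, 3759 of 20037 protein-coding genes had a peak at an end in both control libraries and in neither dexamethasone library, against 153 genes with the opposite pattern. Of these 3759 genes, 1716 shared a window with another gene, a larger share than among all 20037 genes (7271, 36.3%). An end peak can therefore be a neighbour's, more often so in the control-only genes. A peak at an end was listed for 63.4% and 63.3% of genes in control libraries and for 39.7% and 33.1% in dexamethasone libraries. The control-only gene with the highest peaks was ISLR2 (gene ID 57611, chromosome 15, 74100318 to 74141826), with heights of 250 and 260. It was followed by DSCAML1, a cell adhesion gene, with heights of 254 and 217, and PCGF1, a Polycomb group gene, with 207 and 217. HOXC4 and HOXC6, developmental homeobox genes, shared a peak with heights of 197 and 231, and DNAAF19 and FAM187A shared a peak with heights of 211 and 194. HORMAD2, a meiotic gene, had heights of 203 and 183, TMEM68 164 and 250, and LARS1, the cytosolic leucyl-tRNA synthetase gene, 184 and 191.

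Of the dexamethasone-only genes, RSPH10B (gene ID 222967, chromosome 7, 5926136 to 5970851) had the highest peaks, with heights of 53 and 49, followed by PTPRU, a receptor tyrosine phosphatase gene, with 41 and 45. MRPL24, a mitochondrial ribosomal protein gene, had heights of 36 and 36, and PTMS had 37 and 35. Myelin basic protein (MBP) had 32 and 38, the kinase anchor gene AKAP12 32 and 33, SPDYA 38 and 29, FOXH1 31 and 32, SLC26A5 33 and 30, and the zinc transporter gene SLC39A3 30 and 31. Without strand, these end peaks are not shown to lie at promoters. The other splits gave 155 against 95 genes and 93 against 131 genes. With 67582 peaks from each list there were 3133 control-only and 386 dexamethasone-only genes, and 1488 and 303 when a peak anywhere in the gene counted. Without dexamethasone replicate 1 there were 5970 control-only genes, and the dexamethasone-only count was 276 and 260 without control replicates 1 and 2 and 380 and 500 without dexamethasone replicates 1 and 2.

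Among glucocorticoid-induced genes, 15 of the 29 with an end peak in both control libraries had none in either dexamethasone library. They included the prostaglandin receptor gene PTGER4 (heights 96 and 87 in control), BIRC3 (85 and 79), the phosphatase gene DUSP1 (84 and 77) and TSC22D3 (22 and 26), which encodes a glucocorticoid-induced leucine zipper protein. ERRFI1, an EGFR inhibitor gene, was listed in all 4 libraries with heights of 215 and 262 in control and 36 and 41 in dexamethasone libraries, and KLF9 had heights of 54 and 55 at one end of the gene in control and 22 and 20 at the other end in dexamethasone libraries. FKBP5 (gene ID 2289, chromosome 6, 35573590 to 35728583) had a peak at an end in control replicate 2 (height 37) and dexamethasone replicate 1 (18). No end peak was listed for PER1 or for NR3C1, the GR gene, in any of the 4 lists, although 16 and 10 peaks lay inside NR3C1 in control and 10 and 10 in dexamethasone libraries. The control-only share was 51.7% against 31.8% of other genes, an odds ratio of 2.30 with Fisher's exact p = 0.027, which did not pass adjustment over the 11 lists (Benjamini-Hochberg adjusted p = 0.302).

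Genes of glycolysis and lactate handling had end peaks in 96.3% and 92.6% of 27 members in control libraries and 48.1% in each dexamethasone library. The control-only members numbered 10 of 24 and included the lactate transporter gene SLC16A1 (heights 108 and 116), the enolase genes ENO2 (89 and 87) and ENO1 (36 and 51), PFKL (63 and 51) and the pyruvate kinase gene PKM (46 and 45). Of these, ENO2, PFKL and PKM shared a window with another gene. Lactate dehydrogenase A (LDHA) had end peaks in all 4 libraries, with heights of 52 and 63 in control. The highest end peaks in dexamethasone libraries, 24 and 20, lay at the other end of the gene. Dexamethasone replicate 1 also had a peak of height 15 at the end with the control peaks. The lactate exporter gene SLC16A3 had heights of 154, 134, 35 and 32. Of 22 lactylation writers and erasers with end peaks in both control libraries, 7 were control-only, among them SUCLG1 (71 and 76) and the chromatin remodeller gene SMARCA4 (51 and 65). EP300, an acyltransferase gene, had heights of 102 and 115 in control and 21 in dexamethasone replicate 1, with no end peak listed in dexamethasone replicate 2. AARS1, an alanyl-tRNA synthetase gene, was in all 4 lists with heights of 169, 173, 30 and 26.

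Of the cell cycle genes, 11 of 28 were control-only, including the replication helicase genes MCM4 (72 and 120) and MCM5 (82 and 82), TOP2A (58 and 93) and CDC25A (58 and 65), whereas CDK1 was in all 4 lists with heights of 112, 89, 20 and 19. Of cytosolic ribosomal protein genes, 11 of 29 were control-only, including RPL19 (169 and 199). Among ferroptosis and redox genes 9 of 24 were control-only, led by the ferritin light chain gene FTL (131 and 142) and NCOA4 (78 and 109). Epithelial-mesenchymal and matrix genes gave 7 of 21, with SNAI1 (83 and 88) and THBS1 (55 and 78), and inflammatory genes 6 of 20, with CXCL2 (73 and 69), ICAM1 (68 and 71) and RELB (74 and 61). Of the HIF targets, 5 of 21 were control-only, among them ADM (56 and 62) and EPAS1 (27 and 38), while CA9, a carbonic anhydrase gene, was dexamethasone-only with heights of 29 and 26. Of the genes named so far in this paragraph, MCM4, FTL, NCOA4, THBS1, ICAM1, RELB, ADM and CA9 shared a window with another gene. Kidney tubule genes gave 0 of 8, but 5 of 8 without dexamethasone replicate 1 (odds ratio 1.63). Blood and endothelial markers gave 1 of 8 (CD79B, 16 and 14), with the epithelial gene EPCAM dexamethasone-only (13 and 20). Their end peaks were listed for 40.7% and 44.4% of members in control and 44.4% and 37.0% in dexamethasone libraries. None of the 11 lists differed from other genes by Fisher's exact test after adjustment, and only the glucocorticoid-induced list had an unadjusted p under 0.05. For end peaks in all 4 libraries, set against all other protein-coding genes, no list passed either (lowest Fisher's exact adjusted p = 0.202). Without dexamethasone replicate 1 the odds ratio also crossed 1 for inflammatory (1.19), lactylation (1.17), cell cycle (0.98), ferroptosis (0.98) and glycolysis genes (0.98). For matrix genes it went from 1.07 to 1.96. With windows of 2.5 kb, cell cycle genes gave 2 of 29 (odds ratio 0.281) and lactylation genes 2 of 22 (0.379).

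**Figure D2:**
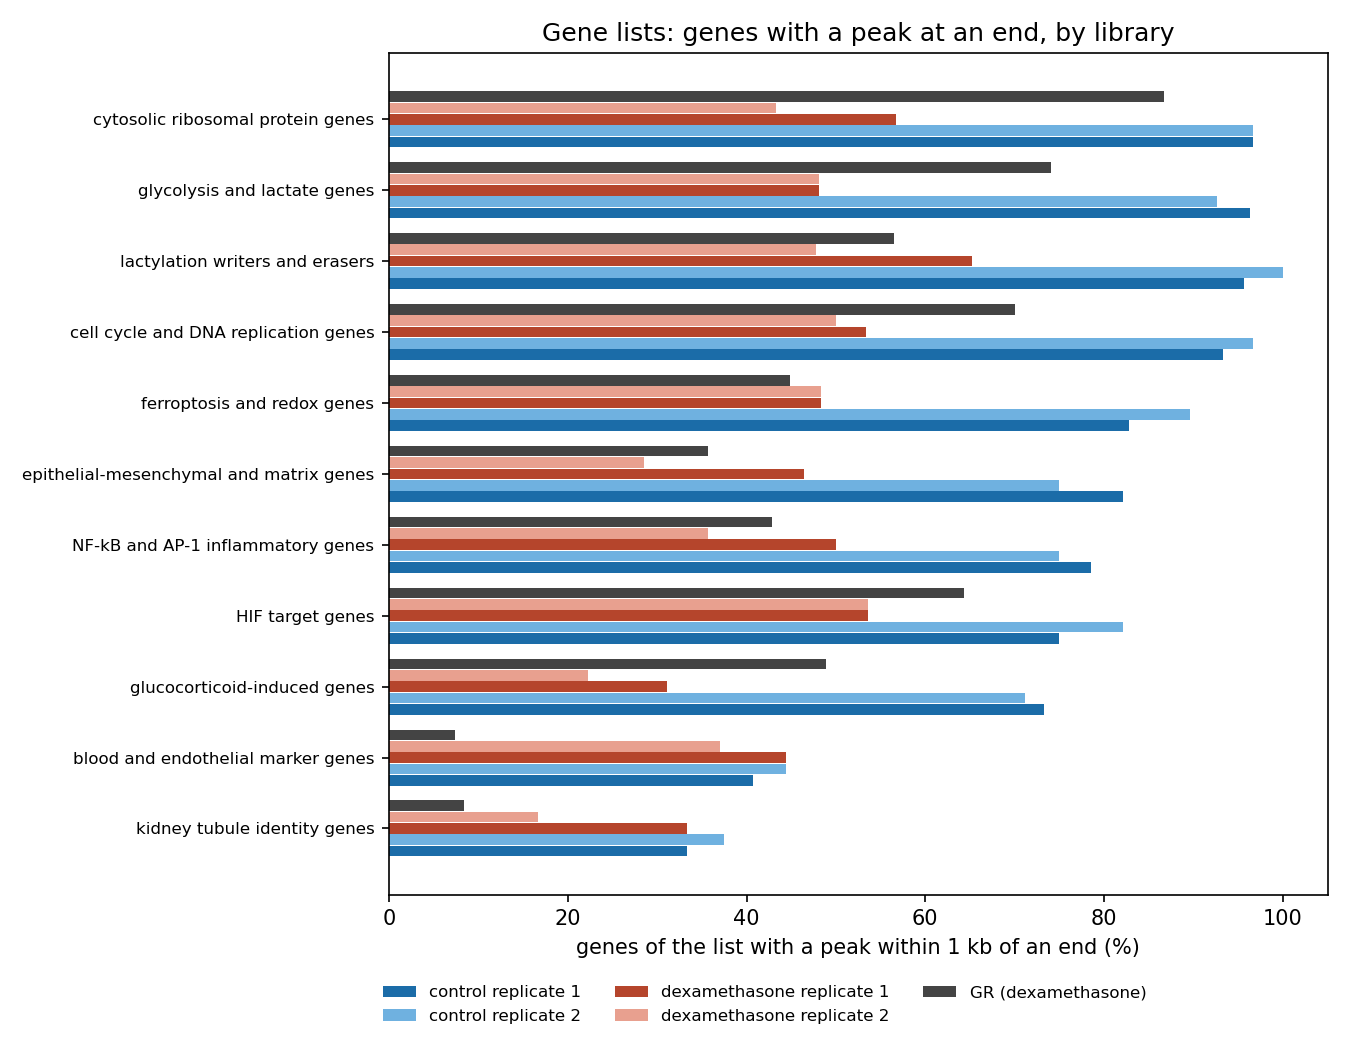
Share of the genes of each of 11 lists with a peak within 1 kb of an end (x axis, percent), with a bar for each of the 4 H4K12la libraries and for the GR library. Glucocorticoid-induced genes had H4K12la end peaks at 73.3% and 71.1% in control and 31.1% and 22.2% in dexamethasone libraries.

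The second comparison asked where GR and H4K12la meet. GR peaks lay mostly at gene ends, with 67.6% of 8065 there (95% exact binomial interval 66.5 to 68.6%), and 32.3% of protein-coding genes had a GR peak at an end. H4K12la peaks of untreated cells overlapped 81.9% and 86.7% of GR peaks, and those of dexamethasone-treated cells overlapped 40.5% and 32.0%. GR peaks placed at random on the same chromosome overlapped 5.80%, 5.26%, 3.61% and 3.09%, so that the observed shares were 14.1, 16.5, 11.2 and 10.4 times higher. The one-sided permutation p was 0.005 in each of the 4 libraries, the smallest that 200 placements can give. When placements kept the share at gene ends, the folds were 4.62, 4.80, 4.55 and 4.40. Neither kind of placement was limited to chromatin open to the transposase, and no control antibody was used here. The folds and p values therefore do not show that the overlap is particular to GR. GR was profiled in 1 library and only with dexamethasone, and the list numbers its rows up to 15183 while 8065 were used here, so a gene without a listed GR peak is not shown to lack one.

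**Figure D3:**
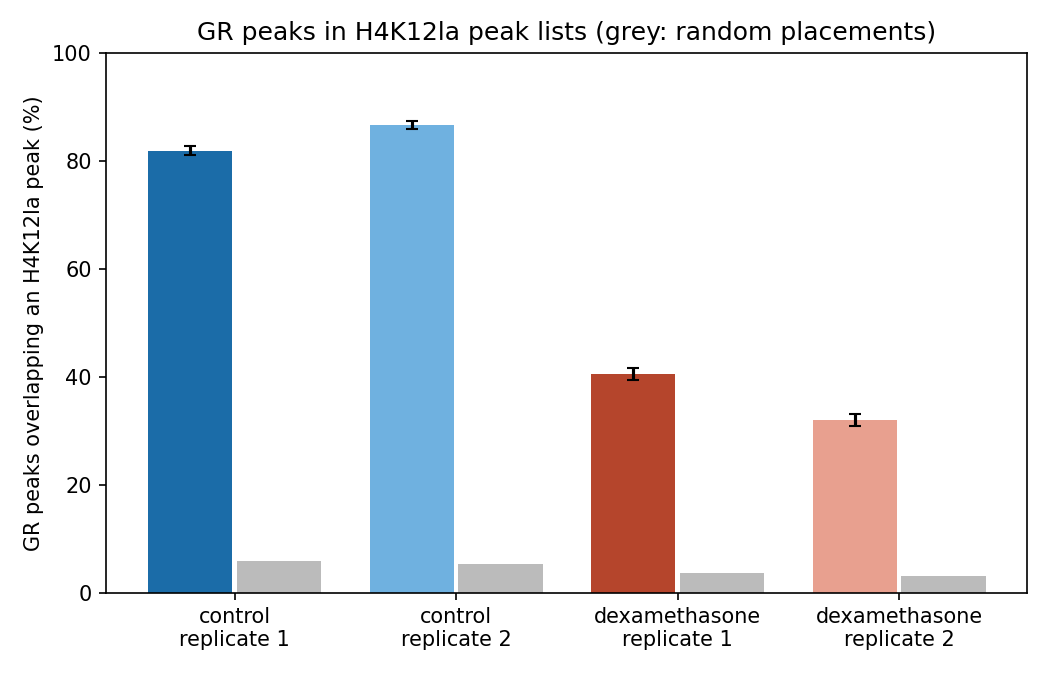
Share of the 8065 GR peaks that overlap an H4K12la peak by 1 bp or more (y axis, percent) in each of the 4 H4K12la libraries (coloured bars, with 95% exact binomial intervals) and the mean of 200 random placements on the same chromosome (grey bars). The shares are 81.9% and 86.7% in control and 40.5% and 32.0% in dexamethasone libraries.

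GR peaks were listed at the ends of 26 of 30 cytosolic ribosomal protein genes (86.7%), against 32.2% of other genes. Glycolysis genes had them at 20 of 27, cell cycle genes at 21 of 30, HIF targets at 18 of 28, lactylation enzymes at 13 of 23 and glucocorticoid-induced genes at 22 of 45. Blood and endothelial markers (2 of 27) and kidney tubule genes (2 of 24) had fewer than other genes. By Fisher's exact test over 11 lists the adjusted p was 1.1e-08 for ribosomal, 5.5e-05 for glycolysis, 1.2e-04 for cell cycle, 0.0021 for HIF, 0.033 for lactylation and 0.033 for glucocorticoid-induced genes, and 0.0078 and 0.026 for the blood and kidney lists. Inflammatory (12 of 28), ferroptosis (13 of 29) and matrix genes (10 of 28) did not pass. The background was all other protein-coding genes, and 5713 of the 20037 genes had no H4K12la end peak in any list. In control replicate 1, H4K12la end peaks ranged from 33.3% of kidney tubule genes to 96.7% of ribosomal protein genes. No test was limited to genes with an H4K12la end peak, so these p values do not show a GR preference among such genes. The GR peak of DUSP1 spanned chromosome 5, 172771022 to 172771576, at the gene's end, and those of KLF9 and EP300 spanned chromosome 9, 70413987 to 70414486, and chromosome 22, 41091340 to 41091831. LDHA had a GR peak at its end (chromosome 11, 18394024 to 18394609) and another inside the gene. No GR peak was listed in FKBP5, TSC22D3, PER1 or NR3C1.

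Ranked by length, since the list gives no height, the longest GR peak covered 5653 bp at chromosome 1, 629147 to 634799, 12512 bp from the nearest protein-coding gene. H4K12la heights there were 608 and 684 in control, with no peak in either dexamethasone list. Regions prone to artefact signal were not filtered out here, so this peak may not reflect GR binding. Other long GR peaks lay at or in MBOAT7 (1708 bp), WDR81 (1434 bp), STK40 (1429 bp), USP5 (1360 bp), SETD5 (1310 bp) and TMEM18 (1309 bp), and 1435 bp, 1357 bp and 1337 bp peaks lay nearest to NDST1, CDK5RAP1 and AMPD3.

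The third comparison asked whether H4K12la regions missing from the dexamethasone lists lay at GR peaks. GR peaks overlapped 2655 of 33206 control-only regions (8.0%), 2233 of 29445 regions in all 4 lists (7.58%) and 2 of 5744 dexamethasone-only regions. Of the 8065 GR peaks, 2818 met H4K12la in both control and neither dexamethasone list, 1958 met it in all 4, and 7 in both dexamethasone and neither control list. Over all regions the odds ratio of control-only against 4-library regions was 1.06 and did not pass the test (Fisher's exact p = 0.056). Regions in all 4 lists were wider (median 1406 bp against 800 bp), and stratified by region width and gene ends the odds ratio was 1.66 (95% interval 1.54 to 1.79). A region joins the peaks of all lists that hold it, so its width depends in part on the class compared. The stratified odds ratios therefore do not settle whether control-only regions met GR peaks more often. At gene ends 33.3% of control-only and 37.2% of 4-library regions met a GR peak (odds ratio 0.844, Fisher's exact p = 5.6e-05), a direction that turned when stratified by width (1.21, 95% interval 1.10 to 1.33). Elsewhere 3.15% and 2.12% did (odds ratio 1.51, Fisher's exact p = 1.2e-13), and the odds ratio stratified by width was 2.93 (2.58 to 3.33). The unstratified odds ratio changed direction with the library left out, at 0.761 without control replicate 1, 0.643 without control replicate 2 and 0.947 without dexamethasone replicate 2, against 1.14 without dexamethasone replicate 1. The stratified odds ratio was 1.41 to 1.92 with each library left out in turn, fits that were added after the data were examined.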

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

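Alternatives chosen after the data were examined were the gene span, a minimum height of 20, the height-matched list test, equal peak numbers for the GR overlap folds, GR peaks at or above their median length, and those run on the stratified GR odds ratio. Of 75 alternative values that answer a comparison, 49 kept their direction and side of the threshold, 20 were larger or newly past it, 2 were smaller and 4 changed direction, all 4 in the unstratified GR odds ratio. Many of the 75 are counts of regions or genes, taken as kept when within 1.5 times of the main count. Such counts have no test and no direction to change, so the tally does not measure how robust they are. None of 77 odds ratios of single lists under an alternative passed adjustment, and 11 of them, in 7 lists, crossed 1. With equal peak numbers, which shorten the longer lists, there were 19273 control-only and 13138 dexamethasone-only regions and 386 dexamethasone-only genes, and the ratio of regions went from 5.78 to 1.47. With a peak anywhere in the gene span counted there were 1488 control-only and 303 dexamethasone-only genes. Leaving out a replicate gave 41665 to 62496 control-only regions, 8013 to 24017 dexamethasone-only regions, 4294 to 5970 control-only genes and 260 to 500 dexamethasone-only genes, because fewer lists had to lack or hold a peak. The replicate numbers share only a number (correlation of deviations -0.0049 over regions), and as a block they gave 70134 and 26691 control-only and dexamethasone-only regions and 6069.5 and 667 genes as means of the pairs. The odds ratio of GR overlap, control-only against 4-library regions, was 1.66 stratified by width and gene ends. Unstratified, it was 1.25 at equal peak numbers, 0.805 with the longer GR peaks, and 0.643 to 1.14 leaving out a replicate. The stratified odds ratio stayed above 1, at 1.59 with equal peak numbers, 1.20 with the longer GR peaks and 1.41 to 1.92 leaving out a replicate. All stratified fits use region width, which depends in part on the class compared, so their stability does not settle the direction. The cause of these changes was not tested. The motif test with its alternatives and the authors' own gene annotation were not run, since neither a sequence nor an annotation was at hand. Unknown depth limits every comparison of peak numbers.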

Other observations

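The tests of lower sensitivity, weaker enrichment, fewer reads, accessible promoters and gene families in this part were chosen only after the result was seen. Of 10 gene families picked by symbol, replication-dependent histone genes had control-only end peaks at 38 of 59 genes (64.4%, Fisher's exact adjusted p = 1.6e-06). Many of these genes lie side by side, and over windows merged between neighbours the share was 22 of 37 (59.5% against 40.1% elsewhere, Fisher's exact adjusted p = 0.186). The protocadherin cluster, cell adhesion genes that share an end, gave 20 of 22 genes but only 2 of 3 merged windows. Defensin and late envelope genes, of skin and innate defence, held 5 dexamethasone-only genes of 58, all late envelope genes (Fisher's exact adjusted p = 8.0e-04), and 5 of 87 merged windows with no control peak, against 1.30% of other such windows (Fisher's exact adjusted p = 0.030). The 5 genes lie in a single cluster on chromosome 1, so they are not independent. Zinc finger genes went the other way, with 0 dexamethasone-only of 533 merged windows with no control peak, against 1.36% of other such windows (Fisher's exact adjusted p = 0.015). Counted as genes, 0 of 517 were dexamethasone-only, which did not pass (Fisher's exact adjusted p = 0.18).

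Chromosomes differed in how many H4K12la peaks the dexamethasone lists held for each control peak. The ratio was 0.784 on chromosome 8 and 0.709 on chromosome 7, against 0.395 on chromosome 13, 0.480 on X and 0.508 on chromosome 17. The highest dexamethasone peak in both libraries lay at chromosome 4, 49709298 to 49711826, with a height of 858 in replicate 1, and a peak starting at or next to chromosome 1, 31431749, was among the 3 highest in all 4 libraries. These values were not tested.

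Gene ends were fewer in the dexamethasone H4K12la lists. Shorter lists are argued against for genes, because at equal peak numbers control-only genes outnumbered dexamethasone-only genes 8.12 times. Lower sensitivity everywhere cannot be told apart from other causes: the common odds ratio of loss at gene ends at matched control height was 1.30 (95% interval 1.25 to 1.35), inside the range of 0.67 to 1.5 set for it, but it pools values from 0.775 in the highest 10% of regions to 1.71 lower down, and 0 of 11 lists stood apart at matched height, which does not show that they fell alike. Fewer reads of the same profile, a narrower form added after that odds ratio was seen, are argued against, because the highest 10% of dexamethasone peaks held gene ends at 1.15 and 1.05 times the share of the whole list, against 2.79 and 2.94 times in control libraries. Weaker antibody enrichment and a true loss of the mark with dexamethasone cannot be told apart, since 1.15 lies between the bounds of 1 and 1.5 set for weaker enrichment and no test here separates it from a loss.

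GR peaks were found at the ends of more ribosomal protein genes (26 of 30) than glucocorticoid-induced genes (22 of 45). Overlapping windows of neighbouring genes are argued against, because 20 of the 26 keep a GR peak in a window that no other gene shares. Tagging of accessible promoters whatever the antibody and GR binding at these promoters cannot be told apart: the difference between the lists (Fisher's exact p = 0.0012) is the pattern itself and tests neither, and no untreated GR library or control antibody was used here.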
